A study of Paralichthys olivaceus with 16 samples.

How the data were processed

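Gene expression was measured in the spleen of olive flounder (Paralichthys olivaceus) on 16 single-colour Agilent arrays, each hybridised with Cy3-labelled RNA of 1 sample. Per the labels, 4 samples were taken before injection (CONT). The other 12 were taken 6 hours or 3 days after injection into the body cavity of formalin-killed Edwardsiella tarda cells, alone (FKC) or with Freund's complete adjuvant (ADJ), with 3 samples per group (FKC6h, ADJ6h, FKC3d, ADJ3d). No group received vehicle or adjuvant alone. The labels do not say whether a sample is 1 fish or a pool, so p-values measure only the spread between these samples, which may be technical.

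The scanner output holds intensity values on a linear scale, extracted with Feature Extraction 10.7.3.1 per the file headers, whereas the submitters' processing notes name version 9.5.3.1 and limma without a version. The processed intensity in the deposited scanner output had been background-subtracted and detrended within each array and was not normalised between arrays, per the file headers and column names. The deposited value table holds log2 values whose recipe the sources do not state. Median spot signals with normexp background correction (offset 16), quantile normalisation, averaging of spots and subtraction of the mean of the 4 controls gave back all 232656 of its values within 1e-08. The direction and scale of that table are therefore known, and its columns have medians from -0.196 to 0.02.

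Each array carried 15197 spots, of which 536 were control spots, and 14481 other probes. Probe names were 14052 of the JFC series, 17 of the POC series and 412 nucleotide accessions. The name columns of the scanner output hold these IDs without gene names, and 0 of them matched the table of 30478 flounder genes used here. No gene is named, and the 27 gene lists chosen beforehand were not tested. The rule for named genes needs gene names. In its place up to 2 probe IDs that rose and 2 that fell are given per comparison: those with the largest change among probes called in both the prespecified and the corrected fit against controls, and in the corrected and the treated-only fit between injected groups, whose groups did not overlap and which were well above background on every array compared. Where no probe was called, the smallest unadjusted p decided. This replacement rule, and so the IDs, were chosen after values were seen.

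The prespecified fit used log2 of the processed signal minus each array's 75th percentile of it, with spots marked as outliers left out and spots of 1 probe averaged. Probes well above background on at least 3 arrays were tested, which left 13621. Group means of all 5 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with Benjamini-Hochberg adjustment within each of 7 contrasts and a threshold of 0.05, two-sided. The design, these settings and most alternatives were fixed before the data were examined. The alternatives were normexp with quantile normalisation, quantile or median scaling, the deposited table, other filters on dim probes, a 2-fold minimum, fits of only the groups compared, slide and replicate number as blocks, intensity trend with robust moderation, array weights, and leaving out each array. The normexp alternative was planned on mean signals; that column is absent from the files, and median signals were used.

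A second set of values, called the corrected set, was chosen after the data and the prespecified counts had been seen, and is not the prespecified result. It leaves out control array 1 and the 1466 spot positions that were unread on the controls, and uses normexp (offset 50) on median signals with quantile normalisation (15 arrays, 12263 probes). An unread spot had a median signal under 15. The offset makes folds of dim probes smaller. Its other versions were the processed signal with the same array and positions left out, and control array 1 put back by 8 spot rows. A further alternative, also added later, took out of every array the median ratio of processed to background-subtracted median signal in bins of spot rows. The closing part on processing gives all counts.

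Groups had 3 or 4 arrays. Both fits were tested on simulated data with 200 of the probes changed. The changes were added to the log2 values of each set after normalisation, so recovery is not on the same scale in both sets. In the corrected set the offset makes a true change of a dim probe smaller than the simulated one, so its recovery is overstated. The simulated noise was independent between arrays and had the same spread on every array, unlike the defects of the control arrays. With all 16 arrays as prespecified, 0% of 2-fold changes were recovered in each of the 6 contrasts simulated, and of 4-fold changes 7% for FKC6h against CONT, 5% for ADJ6h against CONT, 10% for FKC3d and for ADJ3d against CONT, 11% for ADJ6h against FKC6h and 5% for ADJ3d against FKC3d (13621 probes). In the corrected set (12263 probes) the recovery of 2-fold changes was 56%, 58%, 69%, 59%, 70% and 61% in the same order, and of 4-fold changes 95%, 91%, 89%, 94%, 89% and 94%. Shared controls were simulated with unchanged groups 50 times.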

Results

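Spleen gene expression was compared between olive flounder sampled before injection (CONT, 4 arrays) and flounder injected with formalin-killed cells of Edwardsiella tarda, a bacterium that causes edwardsiellosis in fish. The killed cells were given alone (FKC) or with Freund's complete adjuvant (ADJ), a mineral oil emulsion containing killed mycobacteria. Spleens were taken 6 hours (FKC6h, ADJ6h) and 3 days (FKC3d, ADJ3d) later, with 3 arrays per group. The design asks how the spleen responded to the killed cells at each time, and what the adjuvant added. Since no group received the vehicle or the adjuvant alone, differences from CONT include any effect of injection and handling, and differences between ADJ and FKC include any effect of the adjuvant itself.

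On the 12 arrays of injected fish, 11273 to 13640 of 14661 non-control spots were well above background. Control arrays 1 to 3 had fewer such spots (2989, 8649 and 9413), and control array 4, with 12331, lay within that range. Slide 1 held all controls, the 3 FKC6h arrays and ADJ6h array 1, and slide 2 held the other 8 arrays, with 1 scan date per slide. ADJ6h is the only group on both slides, so the term of a fixed slide block rests on ADJ6h array 1 against arrays 2 and 3. Across all non-control spots, unread ones included, log2 median signals of injected arrays correlated with one another at r from 0.912 to 0.989. Control arrays 2 to 4 correlated among themselves at 0.936 to 0.956, and with injected arrays at 0.734 to 0.791. The latter range was 0.899 to 0.97 across probes with unread positions left out, normexp and quantile normalisation (control array 1 put back). Spots and probes are not independent replicates, and these correlations describe the arrays only.

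Control array 1 did not correlate with the injected arrays (r from -0.012 to 0). With its spots displaced by 8 rows, its correlation with the other 15 arrays was 0.792 to 0.932. The prespecified fit keeps control array 1 as read, so its values there are assigned to the wrong probes. Prespecified means of CONT, and the spread shared by the prespecified contrasts, include this error. Mostly in the last spot rows, 839, 1337, 1294 and 1149 spots of control arrays 1 to 4 were unread, against at most 2 on any injected array. Unread spots had median processed signals of 19.2, 163, 180.3 and 2.03 on control arrays 1 to 4. The median log2 fold change of FKC6h against CONT in bins of spot rows ran from -0.95 to -0.002 in the prespecified fit, and from -0.12 to -0.03 in a corrected set chosen after the data were seen (control array 1 and unread positions left out, normexp on median signals, quantile normalisation). Counts from both are given below, the prespecified one first; folds and group means are from the corrected set, and the prespecified log2 changes follow them.

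**Figure D1:**
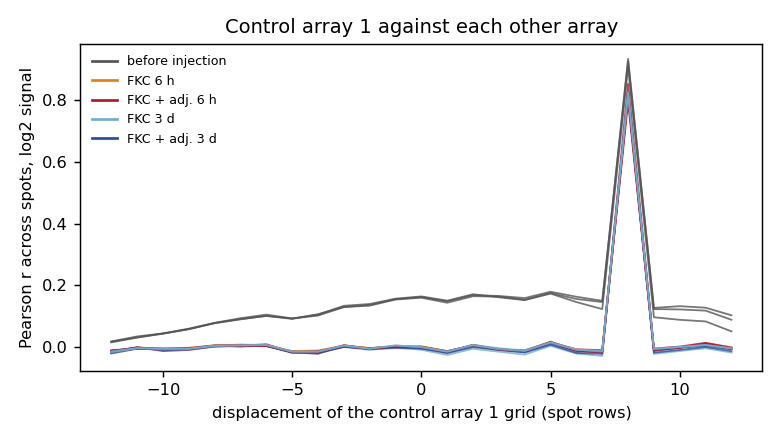
Pearson correlation across spots (log2 signal, vertical axis) of control array 1 with each of the other 15 arrays, as its spot grid is displaced by whole rows (horizontal axis); each line is an array, coloured by group. All lines peak at a displacement of 8 rows, between 0.792 and 0.932.

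**Figure D2:**
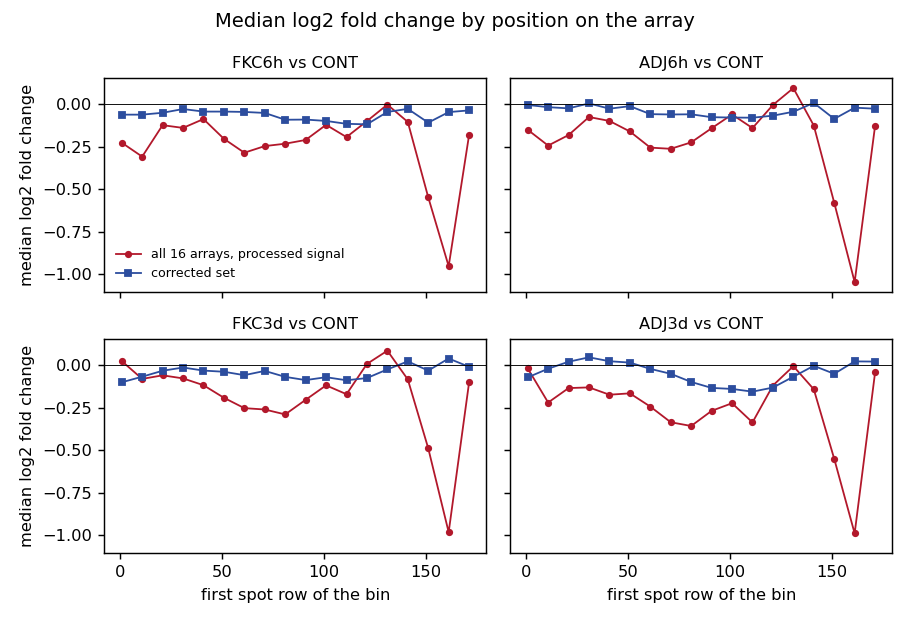
Median log2 fold change against controls (vertical axis) in bins of spot rows (horizontal axis), with 1 panel per injected group; red circles are the prespecified fit and blue squares the corrected set. In the prespecified fit the FKC6h medians run from -0.95 to -0.002, and in the corrected set from -0.12 to -0.03.

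Spleens taken 6 hours after killed cells alone differed from those taken before injection. Probe JFC06162_1_code rose 70.7-fold in FKC6h over CONT (corrected set, 14.28 ± 0.37 against 8.14 ± 0.65 on the log2 scale, SD, n = 3 each). Probe AB198061 rose 58.6-fold (15.52 ± 0.66 against 9.65 ± 0.3). Probe JFC23557_1_code fell by 2.52 ± 0.53 (SE) and JFC23931_1_code fell by 1.9 ± 0.34 on the log2 scale. Their limma adjusted p-values in that set were 3.34e-05, 5.6e-05, 0.0135 and 0.00508, and in the prespecified fit 8.44e-05, 8.44e-05, 0.0208 and 0.0244, with log2 changes of 7.1, 6.2, -3.4 and -1.71 against 6.14, 5.87, -2.52 and -1.9 in the corrected set. Both falls lost their calls in the prespecified fit of slide 1 alone (log2 changes of -3.4 and -1.71, adjusted p = 0.132 and 0.339), JFC23557_1_code also without any 1 of the FKC6h arrays (0.0518, 0.1 and 0.099), and JFC23931_1_code without FKC6h array 1 or 2 (0.167 and 0.119) or control array 3 (0.0583). JFC23557_1_code lost its call in the corrected set with the replicate block too (-2.64 ± 0.6, limma adjusted p = 0.0504). In the prespecified limma fit 526 of 13621 probes were called, 369 higher and 157 lower. In the corrected set 1118 of 12263 were called, 591 higher and 527 lower. Of calls of at least 4-fold, 341 of 459 were higher in the prespecified fit and 149 of 159 in the corrected set, whose offset makes folds of dim probes smaller. Of 365 prespecified calls at read positions, 272 were called again in the corrected set, none in the opposite direction (0). Within slide 1, which held all arrays of this comparison, the 2 counts were 23 (all higher) and 1236, and with slide as a block 534 and 1870. As both groups lie on slide 1, that block leaves the fold changes as they are. It alters only the spread, through the ADJ6h arrays, so its counts say nothing about slide. With control array 1 put back the count was 1021, and 382 in the corrected set with the replicate block. In every comparison with CONT that block leaves out control array 4, so in the corrected set only control arrays 2 and 3 remain. The prespecified count was 153, 202 and 303 without FKC6h array 1, 2 or 3, and 1236 and 1668 without control array 1 or 4. The corrected count was 351 and 389 without FKC6h array 1 or 2, and 692, 647 and 637 without control array 2, 3 or 4.

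With the adjuvant, the same 2 probes were well above CONT at 6 hours. AB198061 rose 57.5-fold (15.49 ± 0.23 in ADJ6h against 9.65 ± 0.3 in CONT, corrected set, SD, n = 3 each), and JFC06162_1_code rose 53.1-fold (13.87 ± 1.05 against 8.14 ± 0.65). JFC18847_1_code fell by 1.32 ± 0.21 and JFC25231_1_code fell by 1.22 ± 0.26 on the log2 scale (SE). Their limma adjusted p-values were 0.000111, 0.000107, 0.00363 and 0.0147 in that set, and 5.29e-05, 5.29e-05, 0.0275 and 0.0254 in the prespecified fit, with log2 changes of 6.54, 6.8, -2.19 and -2.55 against 5.85, 5.73, -1.32 and -1.22 in the corrected set. JFC25231_1_code lies in the bin of spot rows from 151. All probes there had a median log2 change of -0.579 as prespecified and -0.086 in the corrected set. The prespecified fit called 414 probes, 268 higher and 146 lower, and the corrected set 1121, 528 higher and 593 lower. Of calls of at least 4-fold, 239 of 344 were higher in the prespecified fit and 96 of 101 in the corrected set. Of 270 prespecified calls at read positions, 170 were called again. ADJ6h arrays 2 and 3 were on slide 2, so a fixed slide block leaves ADJ6h array 1 alone against the controls, and the lost and kept calls it gives rest on that 1 array. With slide as a block in the corrected set, JFC06162_1_code was higher by 4.57 in place of 5.73 on the log2 scale, and JFC25231_1_code lost its call (-0.73 ± 0.32, limma adjusted p = 0.142, and 0.248 in the prespecified fit). JFC18847_1_code lost its call with that block in the prespecified fit (adjusted p = 0.0638, against 0.00246 in the corrected set), where its log2 change went from -2.19 ± 0.49 to -2.85 ± 0.68. Both falls also lost their calls with only ADJ6h and CONT in the fit (adjusted p = 0.684 and 0.662, and 0.0972 and 0.169 in the corrected set) and, as prespecified, without ADJ6h array 3 (0.132 and 0.136). In the prespecified values the rise of JFC06162_1_code also lost its call with only these groups (6.8 ± 0.75, limma adjusted p = 0.0589). With slide as a block the counts were 158 and 2148, and on slide 1 alone limma called 0 (932 at an unadjusted p under 0.05) and 1684. All 4 counts rest on 1 ADJ6h array assumed to vary like the other groups, and decide nothing. With only ADJ6h and CONT in the fit, the counts were 2 and 57; with control array 1 put back the count was 443, and 335 in the corrected set with the replicate block. Without ADJ6h array 1 or 3 the prespecified count was 255 or 132 and the corrected count 1729 or 555; without control array 1 or 4 the prespecified count was 1546 or 1618, and without control array 2 or 4 the corrected count was 595 or 619.

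At 3 days after killed cells alone, AB198061 was still 33.1-fold above CONT (14.7 ± 0.99 against 9.65 ± 0.3) and AY533022 32-fold (14.78 ± 0.82 against 9.78 ± 0.47, SD, n = 3 each, corrected set). AB198061 and AY533022 read alike on each FKC3d array (13.61 and 13.9, 14.93 and 14.93, 15.55 and 15.51). Whether they measure 1 gene is not known. JFC06162_1_code, at 14.28 ± 0.37 after 6 hours, was at 10.33 ± 0.33. JFC16486_1_code fell by 1.13 ± 0.2 and JFC11873_1_code fell by 0.93 ± 0.11 on the log2 scale (SE). JFC11873_1_code lies in the bin of spot rows from 161. All probes there had a median log2 change of -0.982 as prespecified and 0.04 in the corrected set. The limma adjusted p-values of AB198061, AY533022, JFC16486_1_code and JFC11873_1_code were 0.00105, 0.000272, 0.0162 and 0.00272, and 0.000345, 0.000517, 0.0168 and 0.029 in the prespecified fit, with log2 changes of 5.19, 6.06, -2 and -1.82 against 5.05, 5, -1.13 and -0.93 in the corrected set. The prespecified fit called 227 probes, 137 higher and 90 lower, and the corrected set 430, 241 higher and 189 lower. Of calls of at least 4-fold, 131 of 200 were higher in the prespecified fit and 24 of 26 in the corrected set. Of the 227 prespecified calls 122 lay at unread positions, 97 of the 137 higher and 25 of the 90 lower. At read positions lower calls thus outnumbered higher ones, and 46 of the calls there were called again. All FKC3d arrays were on slide 2 and all controls on slide 1, so a fixed slide block corrects this comparison by the difference of ADJ6h array 1 from arrays 2 and 3, and its lost and kept calls depend on that 1 array. JFC16486_1_code lost its call in the corrected set with slide as a block (-0.41 ± 0.28, limma adjusted p = 0.372), and AB198061, AY533022 and JFC11873_1_code had adjusted p-values of 0.0156, 0.00491 and 0.0298. In the prespecified fit all 4 lost their calls with that block (adjusted p from 0.0865 to 0.541). There the log2 change of JFC16486_1_code went from -2 to -1.13, but those of AB198061, AY533022 and JFC11873_1_code went from 5.19 to 5.42, 6.06 to 6.36 and -1.82 to -1.7, while their SE grew (0.5 to 0.96, 0.63 to 1.22 and 0.37 to 0.7). JFC11873_1_code also lost its call with control array 1 put back (-0.61 ± 0.24, adjusted p = 0.218), with the row-wise factor taken out (0.147) and, as prespecified, without any 1 of the FKC3d arrays (0.124, 0.103 and 0.177), as did JFC16486_1_code without FKC3d array 2 or 3 (0.0932 and 0.142). With slide as a block, estimated through the ADJ6h arrays, the counts were 7 and 1326, and as a random block 169 prespecified calls were left. With only FKC3d and CONT in the fit, limma called 0 (859 at an unadjusted p under 0.05) and 616. The count was 201 with control array 1 put back, and 45 in the corrected set with the replicate block. Without FKC3d array 1, 2 or 3 the prespecified count was 50, 45 or 43 and the corrected count 194, 112 or 16; without control array 1, 3 or 4 the prespecified count was 734, 150 or 1299, and without control array 2, 3 or 4 the corrected count was 163, 276 or 158.

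At 3 days after killed cells with adjuvant, AB198061 was 70.3-fold above CONT (15.78 ± 1.06 against 9.65 ± 0.3) and AY533022 51.4-fold (15.47 ± 0.63 against 9.78 ± 0.47, SD, n = 3 each, corrected set). Whether these 2 probes measure 1 gene is again not known. JFC11873_1_code fell by 0.94 ± 0.11 and JFC25231_1_code fell by 0.93 ± 0.26 on the log2 scale (SE). The 2 falls lie in the bins of spot rows from 161 and 151. All probes there had median log2 changes of -0.989 and -0.55 as prespecified, and 0.023 and -0.05 in the corrected set. The limma adjusted p-values of these 4 probes were 0.000349, 6.02e-05, 0.00176 and 0.0452, and 5.58e-05, 0.000103, 0.0198 and 0.0443 in the prespecified fit, with log2 changes of 6.56, 7.14, -1.84 and -2.3 against 6.14, 5.68, -0.94 and -0.93 in the corrected set. The prespecified fit called 342 probes, 199 higher and 143 lower, and the corrected set 1017, 484 higher and 533 lower. Of calls of at least 4-fold, 180 of 287 were higher in the prespecified fit and 68 of 69 in the corrected set. Unread positions held 102 of the 199 higher and 34 of the 143 lower prespecified calls, so at read positions lower calls outnumbered higher ones. Of 206 prespecified calls at read positions, 103 were called again. These arrays too shared no slide with the controls, and a fixed slide block again depends on ADJ6h array 1. JFC25231_1_code lost its call and most of its change in the corrected set with slide as a block (-0.2 ± 0.41, limma adjusted p = 0.784), and AB198061, AY533022 and JFC11873_1_code had adjusted p-values of 0.00701, 0.00268 and 0.0297. In the prespecified fit all 4 lost their calls with that block (adjusted p from 0.0521 to 0.69). There the log2 change of JFC25231_1_code went from -2.3 to -1.31, but those of AB198061, AY533022 and JFC11873_1_code went from 6.56 to 6.79, 7.14 to 7.44 and -1.84 to -1.71, while their SE grew (0.5 to 0.96, 0.63 to 1.22 and 0.37 to 0.7). JFC11873_1_code also lost its call with control array 1 put back (-0.62 ± 0.24, adjusted p = 0.145) and with the row-wise factor taken out (0.0935). Without any 1 of the ADJ3d arrays both falls lost their calls as prespecified (adjusted p from 0.0731 to 0.183), and JFC25231_1_code did so in the corrected set with the replicate block (0.118). With slide as a block limma called 0 (1580 at an unadjusted p under 0.05) and 1241, and as a random block 289 prespecified calls were left. With only ADJ3d and CONT in the fit, limma called 0 (942 at an unadjusted p under 0.05) and 599. The count was 507 with control array 1 put back, and 252 in the corrected set with the replicate block. Without ADJ3d array 1, 2 or 3 the prespecified count was 95, 72 or 122 and the corrected count 657, 398 or 672; without control array 1 or 4 the prespecified count was 1062 or 1487, and without control array 2, 3 or 4 the corrected count was 472, 652 or 513.

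**Figure D3:**
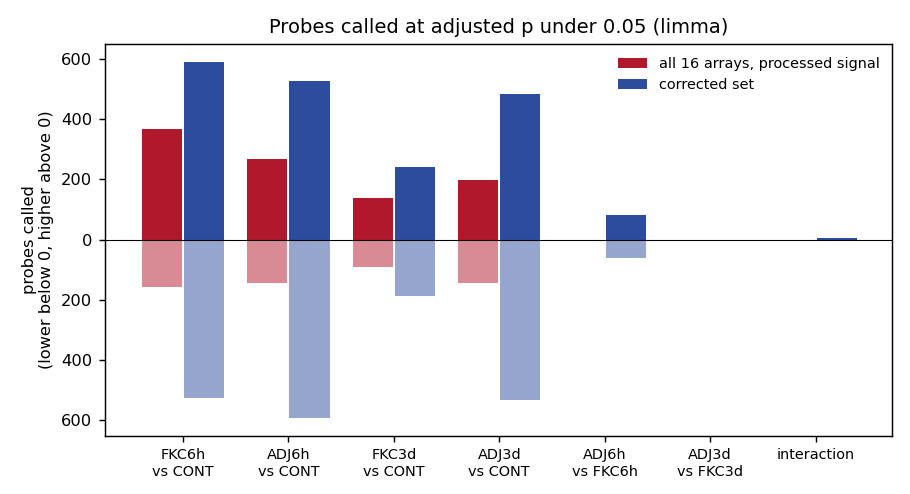
Number of probes called by limma at an adjusted p under 0.05 in each comparison, with probes higher in the first group above 0 and lower ones below 0; red bars are the prespecified fit (13621 probes) and blue bars the corrected set (12263 probes). FKC6h against CONT has 369 higher and 157 lower in the prespecified fit, and 591 and 527 in the corrected set.

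Calls against CONT with and without adjuvant overlapped. At 6 hours 295 probes were called in the same direction in both (211 higher, 84 lower) in the prespecified fit, and 502 (269 higher, 233 lower) in the corrected set. Independent lists would share 8.9 and 50.9. Simulated unchanged groups with the same controls shared 0 on average in both, but unchanged groups give almost no calls, so that count could hardly differ. The simulated noise was independent between arrays and held none of the defects that the control arrays share. At 3 days 205 and 310 were shared, against 2.9 and 17.7 for independent lists and 0 simulated. The correlation of fold changes across probes was 0.776 at 6 hours and 0.816 at 3 days in the corrected set, against 0.497 and 0.499 simulated, and the covariance was 0.255 and 0.18, against 0.038 simulated at both times. In the prespecified fit the correlations were 0.91 and 0.951 (simulated 0.429 and 0.428) and the covariances 2.16 and 2.13 (simulated 0.399 and 0.397). With the controls split 2 and 2 between the groups, 135 to 239 probes were shared at 6 hours and 84 to 184 at 3 days in the prespecified fit, with correlations of 0.155 to 0.402 and 0.139 to 0.416. Every control array had unread spots, so such a split does not remove prespecified calls that unread spots give. With control array 1 put back by 8 rows, the split controls gave 82 to 146 and 4 to 45 shared probes, with covariances of 0.145 to 0.206 and 0.0985 to 0.116.

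The direct comparison of ADJ6h with FKC6h asks what the adjuvant changed at 6 hours, and its calls depended on the values used. AB435094 was 22.8-fold lower with adjuvant (8.48 ± 0.48 against 12.99 ± 0.88, corrected set, SD, n = 3 each) and JFC12482_1_code 20.3-fold lower (8.44 ± 0.48 against 12.79 ± 0.8). In CONT these probes were at 7.31 ± 0.64 and 7.38 ± 0.48, and well above background on 2 of the 3 control arrays in that set. On slide 1, ADJ6h array 1 read 8.53 and 8.45, below the lowest FKC6h array of the same slide at 11.98 and 11.87. AB435094 and JFC12482_1_code read alike on each array compared (13.54 and 13.21 on FKC6h array 1). Whether they measure 1 gene is not known, so they may not be 2 separate results. DQ009987 was 3.84-fold higher with adjuvant and JFC27383_1_code 3.34-fold higher. JFC27383_1_code followed the slides: in the corrected set every slide 1 array read at most 14.86, ADJ6h array 1 among them at 14.78, and every slide 2 array at least 16.09. A fixed slide block leaves ADJ6h array 1 alone against FKC6h, so it does not tell these 4 probes apart (limma adjusted p = 0.1 for DQ009987, 0.0774 for JFC27383_1_code, and 0.00329 for AB435094 and 0.0033 for JFC12482_1_code). The limma adjusted p-values of these 4 probes were 0.00244, 0.00244, 0.0433 and 0.0345 in the corrected set, and 0.679, 0.0736, 0.861 and 1 in the prespecified fit, with log2 changes of -5.18, -5.07, 2.28 and 1.93 against -4.51, -4.34, 1.94 and 1.74 in the corrected set. The prespecified fit called 0 of 13621 probes (416 at an unadjusted p under 0.05). The corrected set called 142, 80 higher and 62 lower with adjuvant, and all 12 of those changed at least 4-fold were lower. With only ADJ6h and FKC6h in the fit, limma called 0 in both (1314 and 1188 at an unadjusted p under 0.05), and with the 12 injected arrays alone, processed signal, it called 67. With slide as a block the counts were 2 and 2308, and on slide 1 alone 0 (536 at an unadjusted p under 0.05) and 1694. All 4 rest on 1 ADJ6h array, whose spread was taken from other arrays, and decide nothing. The corrected count was 7 and 23 without FKC6h array 1 or 2, and 339 without ADJ6h array 3.

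**Figure D4:**
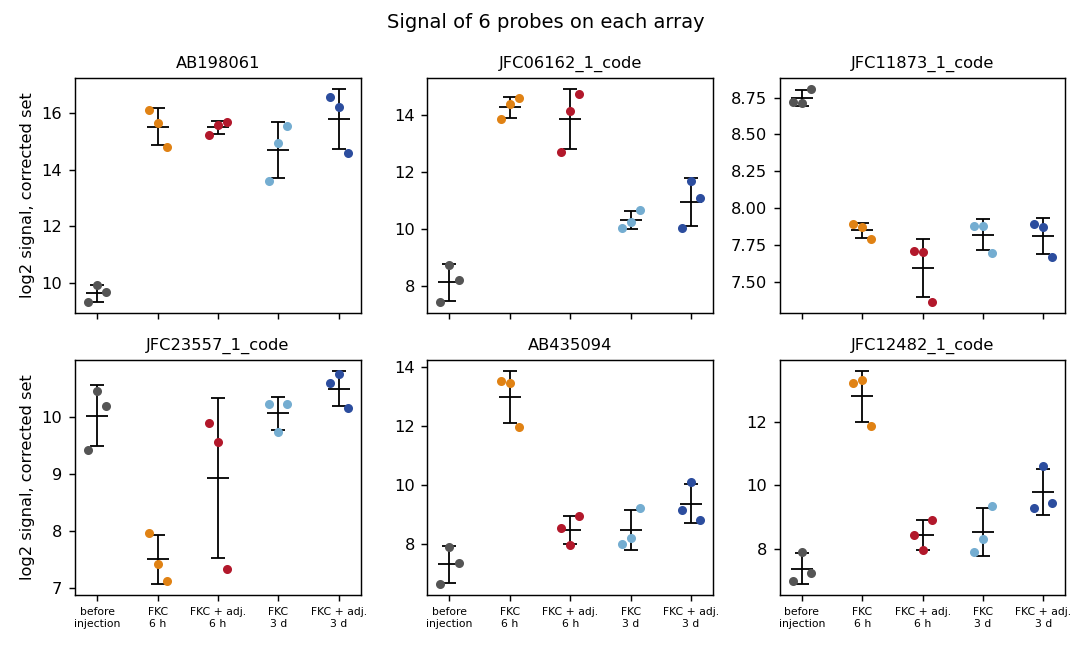
Log2 signal in the corrected set (vertical axis) of 6 probes on each array, by group; points are arrays, and bars are the mean ± SD of 3 arrays. AB435094 and JFC12482_1_code are at 12.99 and 12.79 in FKC6h and at 8.48 and 8.44 in ADJ6h.

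At 3 days no probe passed the test between ADJ3d and FKC3d in either set: limma called 0 in the prespecified fit (68 at an unadjusted p under 0.05) and 0 in the corrected set (841). The probes with the smallest p that were higher with adjuvant were JFC02883_1_code, at 8.71 ± 0.3 against 7.22 ± 0.5, and JFC01552_1_code, at 12.03 ± 0.22 against 11.31 ± 0.11. Those lower were JFC04911_1_code, at 7.93 ± 0.26 against 8.91 ± 0.05, and JFC15206_1_code, at 10.62 ± 0.17 against 11.71 ± 0.18 (log2, SD, n = 3 each). Their limma adjusted p-values were 0.093, 0.382, 0.093 and 0.169, and 1 each in the prespecified fit, with log2 changes of 2.14, 0.56, -1.32 and -1.11 against 1.49, 0.72, -0.98 and -1.1 in the corrected set. All 6 arrays were on slide 2, where limma called 0 in both sets (919 and 1128 at an unadjusted p under 0.05). The corrected count was 1, 2 and 7 without FKC3d array 3, ADJ3d array 2 or ADJ3d array 3.

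Whether the difference made by the adjuvant changed between 6 hours and 3 days was tested as an interaction. JFC12482_1_code moved by 5.61 ± 0.69 and AB435094 by 5.4 ± 0.71 on the log2 scale (SE, corrected set), being lower with adjuvant at 6 hours but not called at 3 days (9.79 ± 0.72 against 8.52 ± 0.76, and 9.37 ± 0.66 against 8.48 ± 0.66). Their limma adjusted p-values were 0.0106 and 0.014, and 0.214 and 1 in the prespecified fit, with changes of 6.49 and 6.36. JFC12482_1_code and AB435094 read alike at 6 hours and may not be 2 separate results. The prespecified fit called 0 probes (231 at an unadjusted p under 0.05) and the corrected set 6, 5 of them higher. With the 12 injected arrays alone 5 were called, and with slide as a block 0 (1072 at an unadjusted p under 0.05) in the prespecified and 1693 in the corrected set, where the 6-hour difference rests on ADJ6h array 1 alone, so these counts decide nothing. The corrected count was 57 without FKC6h array 3, 27, 33 and 98 without ADJ6h array 1, 2 or 3, 29 without ADJ3d array 3, 3 without FKC6h array 2, 2 without FKC3d array 2, and 4 without FKC6h array 1 or ADJ3d array 1.

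**Figure D5:**
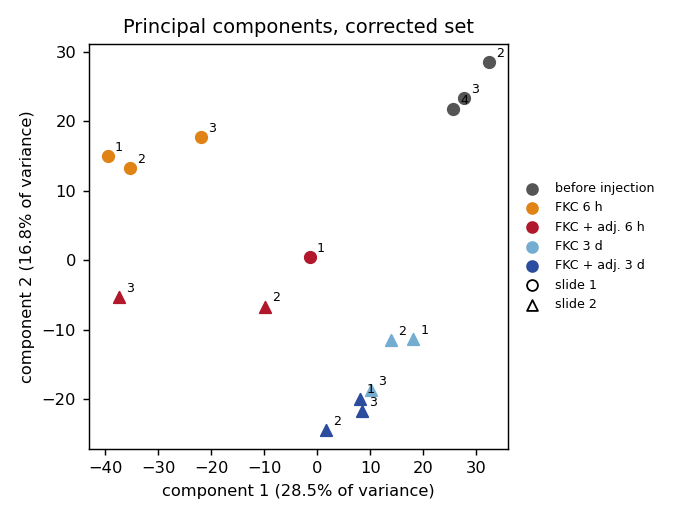
First and second principal components of the corrected set (28.5% and 16.8% of the variance); each point is 1 of 15 arrays, coloured by group, with circles for slide 1 and triangles for slide 2 and the array number beside it. All slide 1 arrays lie above 0 on the second component and all slide 2 arrays below it.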

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

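The tests on control array 1, on unread positions, on distortion along spot rows and on low signal, and all counts of splits, were chosen or redefined after the results had been seen, as was everything in the corrected set; the slide test of ADJ6h array 1 was written beforehand.

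Control array 1 lay far from the other 3 controls in 4 of 16 checks of a single array against its group, where chance gives about 1 in 20. Its brightest negative control spot, in data outside the comparisons, read 31424, its spike-in correlation was 0.4095, the variation of repeated spots was 157.5% and its median correlation with other arrays was -0.004. A grid displaced by whole rows accounts for the lack of correlation, and may account for the other flagged checks. Over 2500 displacements 1 gave r = 0.8183 with FKC6h array 3 and the next best 0.033. Displaced by 8 rows, control array 1 correlated at 0.792 to 0.932 with every other array. The prespecified fit keeps this array as read, so its values there belong to other probes. RNA of a grossly different kind from the other controls is argued against, since the lowest correlation with control arrays 2 to 4 after the array was put back was 0.925, within the 0.899 to 0.97 of injected arrays. An injected sample would pass this test too, so the test does not show that the RNA was like that of the controls. The value lies below the 0.954 to 0.975 of the other controls among themselves, and no biological explanation was tested.

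Calls against controls lay unevenly on the arrays. Unread control spots may account for calls at unread positions, which held 30.6%, 34.8%, 53.7% and 39.8% of the prespecified calls (FKC6h, ADJ6h, FKC3d, ADJ3d) but 10% of the probes tested. For calls at read positions that test is void: 100% were called again in each comparison with those positions and control array 1 left out, but leaving out the positions alone moved their fold changes by a median of only 0.021 to 0.028 (log2). The median log2 ratio of processed to background-subtracted median signal in bins of spot rows ranged over 3.67 on control array 2 and 2.2 on control array 3. It ranged over 0.02 on control array 1, 0.33 on control array 4 and 0.05 to 0.37 on the injected arrays. This distortion along spot rows could account for part of the calls at read positions: with the row-wise factor of the processed signal taken out, 80.3% (FKC6h), 71.9% (ADJ6h), 55.2% (FKC3d) and 71.8% (ADJ3d) were called again, and no 95% interval clears the bounds of 50% and 80% (FKC6h 75.8% to 84.2%, FKC3d 45.2% to 65%). This test replaced a retest on median signals that changed several steps at once (74.5%, 63%, 43.8% and 50% called again, where FKC3d passed the bound for distortion), and the interval was required after FKC6h had come out just above 80%, so neither form decides it and a response to the injection stays open too. The intervals treat probes as independent and are too narrow. With the row-wise factor taken out, 100% of the calls at read positions kept their direction. Those that lost the call had median absolute log2 changes between 2.18 and 2.31 before, and between 1.61 and 1.67 after.

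All 3 ADJ6h arrays correlated less with their own group in the corrected set (0.925, 0.942 and 0.935) than with other groups (0.931, 0.954 and 0.938). Array 1 differs from the others in slide and signal, but on the first principal component array 3 lay furthest off (-37.4, against -1.47 and -9.96 for arrays 1 and 2). FKC6h array 2, on the same slide as ADJ6h array 1, was nearly as dim (75th percentile of processed signal 170.2 against 137.4). It correlated at 0.976 with its own group, so low signal did not set every dim array apart. Low signal of ADJ6h array 1 is a candidate explanation of its difference, which from ADJ6h arrays 2 and 3 correlated across probes at 0.329 with that of control array 1, put back, from the other controls. The value lay little above its bound, which was set after the results. The same difference correlated at -0.194 with FKC6h minus FKC3d, below the bound of 0.1 set against a slide difference. That bound was insufficient, because FKC6h minus FKC3d also holds the time effect, which can hide a slide effect, and no other group spans both slides. A difference between slides therefore stays open.

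Other splits of the same arrays were counted with all arrays in the fit. In the prespecified fit 2 of 35 splits called as many probes as each real split against controls: 526 real and 1139 for the other (FKC6h), 414 and 1166 (ADJ6h), 227 and 979 (FKC3d), and 342 and 992 (ADJ3d). Chance is thus not excluded at a share of 0.05. Each higher split set control arrays 1 to 3 apart from control array 4 and the injected arrays, which points to a structure of the controls. For ADJ6h against FKC6h and ADJ3d against FKC3d, 10 of 10 splits called as many as the real 0 (highest other 0), and 10 splits are too few for a share under 0.05. For the interaction 100 of 100 did (real 0, highest other 0).

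In the corrected set 10 splits are again too few for a share under 0.05. Only the real one (1 of 10) reached 1118 (highest other 0, FKC6h), 1121 (39, ADJ6h), 430 (0, FKC3d) and 1017 (0, ADJ3d) against controls, and 142 (77) for ADJ6h against FKC6h; for ADJ3d against FKC3d 10 of 10 reached 0 (1). For the interaction 6 of 100 splits called at least the real 6 (highest other 15), so chance is not excluded.

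The splits had first been counted with only the groups compared in the fit, a form replaced because its real counts are not the reported ones, and which was the more favourable for the 6-hour comparisons with controls and for the interaction. In the prespecified values it gave 1 of 35 for FKC6h (real 23, highest other 3) and for ADJ6h (real 2, highest other 0), 35 of 35 for FKC3d and ADJ3d (real 0, highest other 1 and 0), 10 of 10 for ADJ6h against FKC6h (real 0, highest other 2) and ADJ3d against FKC3d (real 0, highest other 0), and 2 of 100 for the interaction (real 5, highest other 5). In the corrected set it gave 1 of 10 for 1236, 57, 616 and 599 calls against controls (highest other 0), 10 of 10 for ADJ6h against FKC6h (real 0, highest other 1) and ADJ3d against FKC3d (real 0, highest other 0), and 1 of 100 for the interaction (real 5, highest other 1).

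The interaction test of the adjuvant with time called 5 probes in the fit of the 12 injected arrays, 6 in the corrected set and 0 in the prespecified fit (limma, 231 at an unadjusted p under 0.05). For the 6, chance is not excluded by the splits above, so a difference between the times is not established.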

How the results depend on the processing

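All alternatives that repair the control arrays, and all corrected-set values, were added after the data and prespecified counts had been seen; the others were fixed before. Counts follow the order FKC6h, ADJ6h, FKC3d, ADJ3d against CONT (prespecified 526, 414, 227, 342), then ADJ6h against FKC6h (0), ADJ3d against FKC3d (0) and the interaction (0). ADJ3d against FKC3d was 0 by limma in every setting (68 at an unadjusted p under 0.05 as prespecified) except control array 1 put back (2), and 1, 2 and 7 in the corrected set without FKC3d array 3, ADJ3d array 2 or ADJ3d array 3. Unless the setting itself shows it, the cause was not tested.

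Normexp with quantile normalisation gave 1418, 1376, 1092 and 1364, then 13 and 5 (interaction), and the values as deposited 1368, 1324, 1051 and 1305, then 13 and 5. Quantile normalisation alone, and trend with robust moderation, gave 1 for ADJ6h against FKC6h. Requiring signal on all 16 arrays, which leaves 1630 probes, gave 3, 2, 1 and 1. Only the groups compared gave 23, 2, 0 and 0, and 5 for the interaction. Slide as a block, resting on ADJ6h array 1 against arrays 2 and 3, gave 158, 7 and 0 for ADJ6h, FKC3d and ADJ3d, and 2 for ADJ6h against FKC6h; slide 1 alone gave 23 and 0. Array weights gave 4503, 3312, 4246 and 3339, then 463 and 88. Leaving out 1 array gave 153 to 1668, 132 to 1618, 43 to 1299 and 72 to 1487, and 0 to 0 between injected groups.

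The 3 repaired versions were: positions and control array 1 left out, 1150, 1597, 588 and 946, then 49 and 2 (interaction); corrected set, 1118, 1121, 430 and 1017, then 142 and 6; control array 1 put back, 1021, 443, 201 and 507, then 65, 2 and 7. Within the corrected set, slide as a block gave 1870, 2148, 1326 and 1241, then 2308 and 1693, with the slide term resting on the same arrays. Only the groups compared gave 1236, 57, 616 and 599, and 5 for the interaction. On the prespecified signal, the 12 injected arrays alone gave 67 and 5, and taking out the row-wise factor gave 687, 582, 328 and 573. Shared calls at 6 hours and 3 days were 295 and 205, 502 and 310 in the corrected set, at lowest 135 and 84 with split controls, and at lowest 82 and 4 with split controls and control array 1 put back.

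Replicate numbers did not pair the arrays: 1 of 30 same-number pairs correlated over 0.1 (from -0.366 to 0.107), and 5 of 26 in the corrected set (from -0.409 to 0.289). The replicate block gave 1470, 1392, 1174 and 1318. Number 4 occurs only among controls, so the block leaves control array 4 out, in the corrected set too, and lost calls there may come from the lost control. In the corrected set it gave 45 for FKC3d, 26 for ADJ6h against FKC6h and 2 for the interaction, with 382, 335 and 252 for the others against controls.

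Calls that were higher made up 70.2%, 64.7%, 60.4% and 58.2% as prespecified, 74.5%, 71.5%, 80.8% and 71.7% with normexp and quantile, 78.4%, 73.6%, 72.4% and 74.8% with quantile, 74.8%, 72.4%, 81.2% and 72.6% in the deposited table, and 52.9%, 47.1%, 56% and 47.6% in the corrected set. More calls were lower than higher without control array 4 (754 higher and 914 lower, 720 and 898, 483 and 816, 618 and 869) and with the replicate block (643 and 827, 588 and 804, 414 and 760, 521 and 797). Unread positions held 97 of the 137 higher prespecified calls in FKC3d and 102 of 199 in ADJ3d. At read positions lower calls outnumbered higher ones in these 2 comparisons, but not in FKC6h or ADJ6h. The median of all log2 fold changes moved from -0.23, -0.19, -0.18 and -0.24 to 0.04, 0.06, 0.07 and 0.04 with quantile. Of 689 values of the named probes under alternatives, 563 kept direction and side of the threshold, 75 lost the call, 51 gained one and 0 reversed. These probes had been picked for the same direction in 2 fits of these data, so their kept direction was largely fixed by the choice. The 27 gene list shifts were not run, for want of gene names. Spots well above background were 20.4% on control array 1 and 59% on control array 2.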

Other observations

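All tests in this part were added after the data had been seen.

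After killed cells alone, 1279 probes differed between the 6-hour and 3-day arrays (671 higher and 608 lower at 3 days, limma, injected arrays, normexp and quantile). Of these, 19 were higher and 115 lower at 3 days by at least 4-fold. FKC6h was on slide 1 and FKC3d on slide 2, so time and slide cannot be separated there. With adjuvant 48 probes differed between the times (15 higher, 33 lower), 101 without ADJ6h array 1, and 9 within slide 2 (3 arrays against 2). On the processed signal the counts were 998 (409 higher and 589 lower, 97 and 268 of them at least 4-fold) and 101 (18 higher, 83 lower). Of those 9 probes 7 were also called after killed cells alone, all in the same direction, against 0.4 for independent lists, and fold changes of the comparisons correlated at 0.506 across probes. Whether the adjuvant altered the change with time is the interaction given in the report.

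In the corrected set 119 probes called in FKC6h were called in the same direction in FKC3d, against 19.7 for independent lists, and 471 in ADJ6h and ADJ3d, against 46.6. The correlations across probes were 0.494 and 0.698, where simulated unchanged groups with the same controls gave 0.495 and 0.497, and the covariances were 0.127 and 0.197 against 0.0378 and 0.0379. The difference between the FKC and ADJ overlaps was not tested.

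Probes named by a nucleotide accession were called more often than the rest in FKC6h and ADJ3d of the corrected set, also with brightness matched, but not in ADJ6h, nor in FKC3d with brightness matched. In FKC6h 16.8% of 315 such probes were called, against 8.91% of the others (odds ratio 2.07, Fisher's exact test over 4 comparisons, adjusted p = 3.32e-05). They were also brighter (median log2 signal 9.36 against 7.65). Stratified over 10 brightness bins, the odds ratios were 1.92, 1.01, 1.36 and 1.67 for FKC6h, ADJ6h, FKC3d and ADJ3d, with adjusted exact p-values of 0.000508, 0.92, 0.277 and 0.0069. Probes are not independent, so these p-values are too small.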
